A study of Bifidobacterium bifidum PRL2010 with 6 samples.

How the data were processed

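Transcript levels of *Bifidobacterium bifidum* PRL2010, a bacterium of the human gut, were measured on 6 single-colour CombiMatrix oligonucleotide arrays, 2 for each of 3 culture conditions. Per the labels' protocols, cultures were grown without oxygen at 37 °C in MRS, a rich broth for lactic acid bacteria, with 0.05% cysteine hydrochloride. The reference cultures received nothing further. The second group received cholesterol at 100 µg/ml at an optical density of 0.6, and the third received the same amount of cholesterol with 5% oxgall, a dried preparation of ox bile. Both treated groups were then incubated for 180 minutes. The labels of the MRS group give neither an optical density nor an incubation time. RNA was extracted with a macaloid and phenol method, treated with DNase, and 5 µg was amplified and labelled with Cy5, per the labels' protocols. These protocols speak of 1 shared pool of RNA for labelling, while the labels also state duplicates per condition. Whether the 2 arrays of a group are technical repeats or separate cultures is thus not known. Every p-value for a change between groups measures only the spread between these arrays.

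Each scanner table deposited by the authors holds, per the file headers, the median, mean and standard deviation of the foreground intensity of 1902 probes, on a linear scale and with no background column. The scanner software and its background handling are not given in the sources used here. Each *B. bifidum* probe was read from 21 to 26 features, of which at most 2 were excluded on any array. Of the 1902 probes, 1822 carry a *B. bifidum* identifier, with 1 probe for each identifier, and 80 do not. The latter comprise 54 probes of the manufacturer and 26 submitted probes, and 47 of the 80 are negative controls by their names. The table of processed intensities deposited by the authors was set against the scanner values of each array. Over the *B. bifidum* probes every column ranked exactly as the median intensity of its own array did, with a Spearman correlation of 1, and the distributions of the columns nearly coincided. Their medians over these probes were 250.25 to 251.75, and values of equal rank spanned 0.67% of their mean across the columns in the median case. The values are thus on a linear scale with no gene centred and close to what quantile normalization gives, while 75 of the 80 other probes stood at their scanner value within 0.01. Over all its probes, those left at scanner values included, the column medians of that table were 252.94 and 254.80 for MRS, 247.55 and 249.67 for cholesterol, and 247.75 and 247.55 for cholesterol with oxgall. It served as an alternative to the scanner values.

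The median foreground intensities were corrected with the normexp method of limma 3.58.1 in R 4.3.3, with an offset of 50 and the foreground alone, fitted on all probes. After log2 transformation the 1822 *B. bifidum* probes were quantile normalized between the 6 arrays. All 6 arrays entered 1 linear model with the group as its only term, since 2 arrays per group leave 3 residual degrees of freedom, to which the empirical Bayes prior added 5.78. The 3 contrasts were cholesterol against MRS, cholesterol with oxgall against MRS, and cholesterol with oxgall against cholesterol. A probe was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 1822 probes. All adjusted p-values are from limma unless another test is named. An exact permutation test of 2 arrays against 2 cannot give a two-sided p under 0.33 for any single probe. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.173.

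A probe was taken as above background on an array where its scanner intensity exceeded a limit. That limit was the median of the 47 negative controls plus 3 median absolute deviations, each scaled to estimate a standard deviation. This limit was chosen after the data had been examined, because some negative controls were bright on the treated arrays. With the 95th percentile of the negative controls as the limit, 832 and 973 probes passed on the MRS arrays. On the treated arrays 337 to 405 then passed. Counts by background, and the bounds below, depend on this choice. Where a probe was not above background on either array of a group, its change is given as "at least N-fold". That bound sets the mean of the bright group against the mean, per array, of the higher of the lowest level among probes above background and the probe's own level. Such bounds rest on the normexp and quantile values and can lie above a fold from another processing. Counts of probes past 2-fold or 4-fold take the fitted fold where both groups were above background and the bound where 1 was not, and leave out probes above background in neither. Probes at the scanner ceiling of 65535, at most 4 on any array, were kept.

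The reference gene table provided covers another strain, with 1875 genes, and 0 of the 1822 identifiers matched it. The scanner tables pair no identifier with a gene name or product. The 26 gene lists fixed before the data were examined, bile salt hydrolases and transporters among them, thus had 0 members, and the planned tests of lists were not run. The rule for named genes, fixed at the same time, took the 10 largest rises and the 10 largest falls of each comparison among called probes whose groups did not overlap. Without gene names, only the largest rise and the largest fall of each comparison against MRS are named, 4 identifiers in all, and the others are given as ranges. Genome positions of the probes were not analysed here.

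For the similarity of the responses, 100 sets of 6 unchanged arrays were simulated with the observed spread, so that both simulated comparisons shared their MRS arrays. The pipeline was also tested on simulated arrays. In 5 simulations of cholesterol against MRS, 200 of 1822 probes were changed, all drawn from those above background on both MRS arrays. The signal of every simulated array was built from MRS replicate 2. Dimmer probes and a differing range of signal were thus not tested. Of the 4-fold changes 98.8% were recovered, and of the 2-fold changes 70%. Of the simulated calls 10.2% fell on unchanged probes, a larger share than the limit of 0.05. A 4-fold change was estimated at 1.50 on the log2 scale. For cholesterol with oxgall, 98.8% and 71.6% were recovered against MRS, and 99.4% and 69.8% against cholesterol, with 10.2% and 8.14% of calls on unchanged probes. Alternatives fixed before the data were examined were median centring, 75th percentile scaling, cyclic loess, no background correction, an offset of 16, the processed values of the authors, a filter on dim probes, a replicate block, the 4 arrays of a comparison alone, another variance prior, a 2-fold limit and leaving out each array. Alternatives added later were the mean over features, only probes above background on all 6 arrays, and the calls made under all 4 scalings. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.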

Results

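The arrays were made to find out whether and how *B. bifidum* PRL2010 adjusts its transcription to cholesterol, with and without oxgall, whose bile salts stand for the conditions of the intestine. Transcript levels were compared between MRS cultures, cultures given cholesterol and cultures given cholesterol with oxgall, with 2 arrays per group. Of 1822 *B. bifidum* probes, 499 and 656 were above background on the 2 MRS arrays, 640 and 537 on the cholesterol arrays, and 605 and 644 on the arrays of cholesterol with oxgall. Across the 6 arrays, 341 probes were above background everywhere and 941 nowhere. The MRS arrays had the narrower range of signal. The 95th percentile of the *B. bifidum* probes exceeded the median negative control by 443.7 and 882.4 intensity units in MRS, by 1251 and 1503.3 with cholesterol, and by 1333.8 and 1021.9 with cholesterol and oxgall. Arrays of 1 group correlated across probes at Pearson's r of 0.963 for MRS, 0.976 for cholesterol and 0.982 for cholesterol with oxgall. Arrays of different groups correlated at 0.753 to 0.892. The first principal component, with 67.2% of the variance, placed the cholesterol arrays between the MRS arrays and those of cholesterol with oxgall, and the second, with 21.1%, set the cholesterol arrays apart from both.

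The first comparison asked how cells responded to cholesterol alone. Against MRS, 265 probes rose and 284 fell with cholesterol, together 30.1% of the 1822 probes. The rises were the larger changes. Counting measured folds, and bounds where 1 group was not above background, 79 probes rose at least 2-fold and 18 at least 4-fold, while 33 fell at least 2-fold and 0 at least 4-fold. The 10 largest rises spanned fitted log2 fold changes of 2.33 to 2.91, with adjusted p-values up to 0.00041, and the 10 largest falls spanned -1.20 to -1.56, with adjusted p-values up to 0.019. Among the 10 rises 2 were not above background in MRS, so that their fitted values are not measured folds, while all 10 falls were above background in both groups. Of the probes that rose, 106 were above background in only 1 of the 2 groups, that is on at least 1 of its arrays. The same held for 72 of those that fell. Which group it was is not separated in these counts.

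The largest rise was that of BBIF01554, measured by the probe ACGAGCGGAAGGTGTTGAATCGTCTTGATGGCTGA. It stood at a normalized log2 intensity of 6.60 ± 0.042 (SD, n = 2) in MRS, where it was not above background, and at 9.51 ± 0.455 (SD, n = 2) with cholesterol, a rise of at least 3.85-fold. Its fitted log2 fold change was 2.91 ± 0.22 (SE), with an adjusted p of 0.000109 by limma. Over the alternatives it ranged from 1.91 with the authors' processed values, or 3.75-fold and so below the bound, to 3.46 with an offset of 16. The largest fall was that of BBIF01961, measured by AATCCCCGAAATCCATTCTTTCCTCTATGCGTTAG, from 9.94 ± 0.299 (SD, n = 2) to 8.38 ± 0.041 (SD, n = 2). Its log2 fold change was -1.56 ± 0.179 (SE), with an adjusted p of 0.00056 by limma. With median centring in place of quantile normalization its change was -0.60 and no longer passed the test.

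The share of rises and falls depended on how the arrays were scaled to each other. With median centring 268 probes rose and 49 fell, with 75th percentile scaling 171 rose and 850 fell, and with cyclic loess 212 rose and 182 fell. Called under all 4 scalings were 117 rises and 19 falls. Scaling to the 75th percentile shifted the median of all probes to -0.588 on the log2 scale in this comparison, to -0.307 for cholesterol with oxgall against MRS, and to 0.295 for cholesterol with oxgall against cholesterol. With 75th percentile scaling, limma estimated 1 variance for all probes. Leaving out cholesterol replicate 1 left 155 rises and 113 falls, and leaving out replicate 2 left 148 and 108. Leaving out replicate 1 or 2 of cholesterol with oxgall, outside this comparison but in the same fit, left 179 or 176 falls. Neither group was above background for 1024 of the 1822 probes. Of these, 134 were among the 549 called probes, and no fold is given for them.

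**Figure D1:**
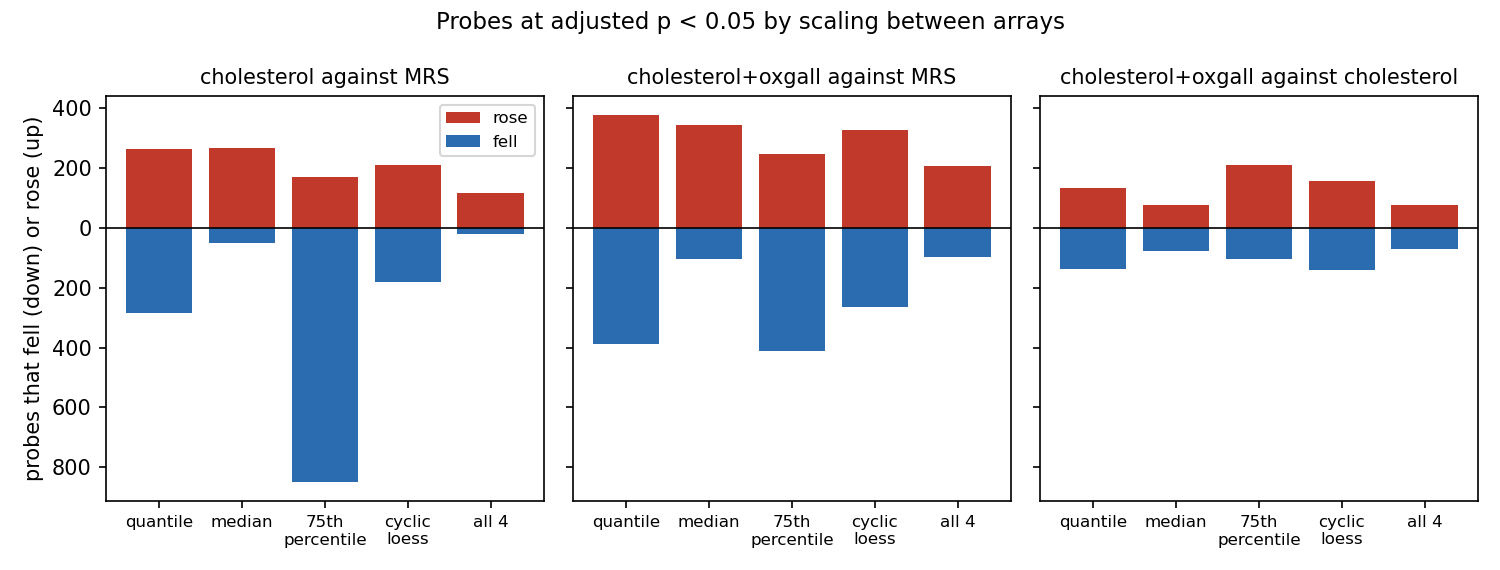
Number of probes that rose (red, up) or fell (blue, down) at an adjusted p under 0.05 by limma in each comparison, under quantile normalization, median centring, 75th percentile scaling and cyclic loess, and under all 4 at once. With cholesterol against MRS the falls range from 49 to 850, and 117 rises and 19 falls were called under all 4.

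The second comparison asked how cells responded to cholesterol and oxgall given together. No group received oxgall alone, so the effect of cholesterol in the presence of oxgall cannot be measured here. Against MRS, 378 probes rose and 389 fell, together 42.1% of those measured. These were more than with cholesterol alone, an order that turned with 75th percentile scaling, where 1021 probes changed with cholesterol and 658 with cholesterol and oxgall. By measured folds and bounds, 124 probes rose and 118 fell at least 2-fold, and 31 rose and 29 fell at least 4-fold. The 10 largest rises spanned fitted log2 fold changes of 2.73 to 4.73, with adjusted p-values up to 6.7e-05, and the 10 largest falls spanned -2.77 to -4.61, with adjusted p-values up to 0.00014. Of these, 4 rises and 7 falls were not above background in 1 of the groups. Probes above background in only 1 of the 2 groups, whichever it was, made up 154 of the rises and 140 of the falls. Among the 341 probes above background on all 6 arrays, 70 rose and 72 fell at least 2-fold, against 52 and 17 with cholesterol alone.

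The probe of BBIF01434, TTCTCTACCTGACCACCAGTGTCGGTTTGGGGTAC, had the largest rise, from 8.41 ± 0.127 (SD, n = 2) in MRS to 13.14 ± 0.57 (SD, n = 2), or 26.5-fold. Its log2 fold change was 4.73 ± 0.25 (SE), with an adjusted p of 5.79e-06 by limma. Its size depended on the scaling, with a log2 fold change of 5.36 with cyclic loess, 5.66 with 75th percentile scaling and 6.01, or 64.4-fold, with median centring, and the lowest value was 4.08 with the mean over features. With cholesterol alone its log2 fold change was 0.98 ± 0.25 (SE), with an adjusted p of 0.0193 that did not pass under 7 of the alternatives. Over all alternatives run, this log2 fold change ranged from 0.49 with the mean over features to 1.66 with median centring. The name of this probe ends in an X and a number, as do those of 54 probes in all, a mark whose meaning the headers do not explain. In this comparison 42.6% of these and 42.1% of the other probes changed. The probe of BBIF01704, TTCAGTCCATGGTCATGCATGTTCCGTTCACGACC, had the largest fall, from 11.18 ± 0.133 (SD, n = 2) to 6.57 ± 0.369 (SD, n = 2), where it was not above background. It fell at least 13.1-fold, with a log2 fold change of -4.61 ± 0.196 (SE) and an adjusted p of 1.9e-06 by limma. This value ranged from -5.25 with an offset of 16 to -3.42 without background correction, or 10.7-fold and so below the bound. With cholesterol alone the log2 fold change of BBIF01704 was -1.08 ± 0.196 (SE), with an adjusted p of 0.00463, and with median centring it was -0.31 and did not pass. The probes named above for cholesterol alone also changed. BBIF01554 rose at least 3.4-fold, with an adjusted p of 3.42e-05, and BBIF01961 fell at least 5.53-fold, with an adjusted p of 9.81e-06. Their fitted log2 fold changes of 2.73 and -3.04 ranged from 1.76 to 3.28 and from -3.48 to -2.16 over the alternatives.

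**Figure D2:**
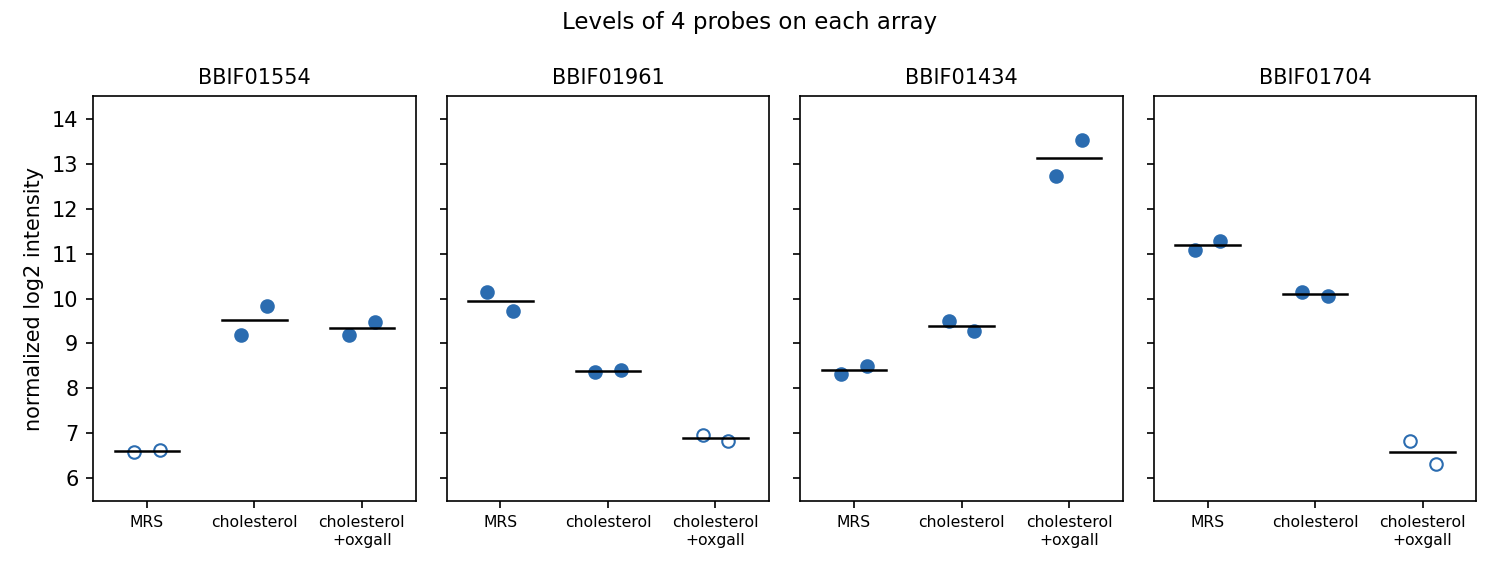
Normalized log2 intensity of 4 probes on each of the 6 arrays, with 2 arrays (points) and their mean (line) per group. Filled points are above background and open points are not. BBIF01554 was at 9.51 and 9.34 in the treated groups, while BBIF01434 and BBIF01704 moved furthest with cholesterol and oxgall, to 13.14 and 6.57.

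Median centring gave 344 rises and 105 falls in this comparison, 75th percentile scaling 247 and 411, and cyclic loess 326 and 264. Called under all 4 scalings were 208 rises and 98 falls. Leaving out replicate 2 of cholesterol with oxgall left 246 rises and 235 falls, and leaving out replicate 1 left 246 falls. Neither group was above background for 960 of the 1822 probes, and 184 of these were among the 767 called probes. No incubation time is given for the MRS cultures, so neither comparison against MRS is known to be matched in time.

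The responses to the treatments were set against each other across probes. Most probes that rose with cholesterol also rose with cholesterol and oxgall. This held for 223 probes, 84.2% of the cholesterol rises, where independent lists would share 55. Falls were shared by 197 probes, 69.4% of the cholesterol falls, where independent lists would share 60.6. Under all 4 scalings, 92 shared rises and 3 shared falls were called. Without cholesterol replicate 1 or 2, the shared rises numbered 148 and 139 and the shared falls 88 and 76. Without replicate 1 or 2 of cholesterol with oxgall, the shared falls numbered 112 and 103. In opposite directions, 15 probes fell with cholesterol and rose with cholesterol and oxgall, and 1 did the reverse. The log2 fold changes correlated at Pearson's r of 0.72 and Spearman's rho of 0.764 across the 1822 probes, which are not independent replicates. Because both comparisons used the same MRS arrays, simulated arrays without any change gave a median r of 0.502. Those unchanged arrays also gave a median of 0 shared rises and 0 shared falls. Few probes are called where nothing changes, so these counts cannot show what the sharing adds to the calls. Part of the shared calls may come from the shared arrays. The covariance was 0.392 against 0.0182 in the simulation, a difference of 0.374. This argues against the spread between the shared MRS arrays as the main source of the correlation. With a separate single MRS array for each comparison, r was 0.566 to 0.666. An offset common to both MRS arrays, such as another incubation time, was not simulated. It would also remain between separate MRS arrays, so none of these values can test it.

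**Figure D3:**
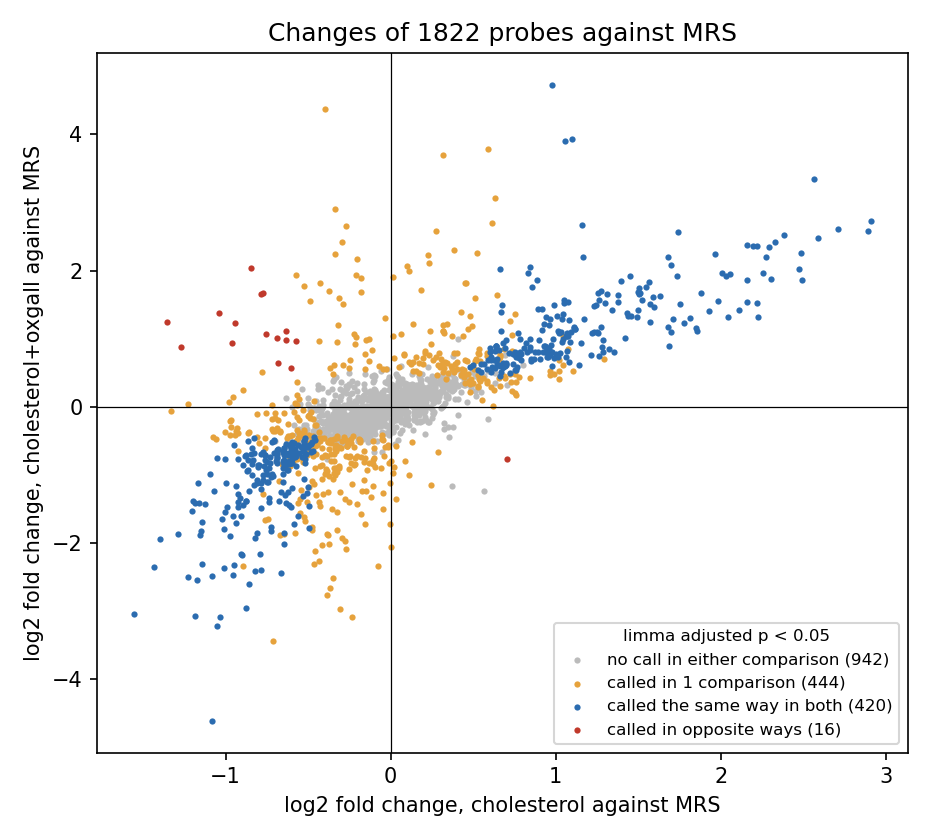
Log2 fold change of each of 1822 probes with cholesterol (horizontal) and with cholesterol and oxgall (vertical), both against MRS, coloured by the calls at an adjusted p under 0.05 by limma. 420 probes were called the same way in both comparisons, 16 in opposite ways, 444 in 1 comparison and 942 in neither.

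The third comparison asked what oxgall added, in cultures that had the same cholesterol and the same 180 minutes of incubation. With oxgall 132 probes were higher and 138 lower than with cholesterol alone, together 14.8% of those measured. By measured folds and bounds, 61 were higher and 62 lower at least 2-fold, and 22 were higher and 9 lower at least 4-fold. Among the 341 probes above background on all 6 arrays, 32 were higher and 46 lower by at least 2-fold. The 10 largest rises spanned fitted log2 fold changes of 2.72 to 4.78, with adjusted p-values up to 0.00015, and the 10 largest falls spanned -2.08 to -3.53, with adjusted p-values up to 0.00085. Of these, 3 rises and 4 falls were not above background in 1 of the groups. Of the 10 largest rises against cholesterol, 7 were also among the 10 largest against MRS, and the same number held for the falls. Both comparisons use the same arrays of cholesterol with oxgall, so part of this overlap can come from those arrays. The 10 largest rises with and without oxgall against MRS shared 2 probes, and the 10 largest falls shared 1.

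BBIF01434 was 13.4-fold higher with oxgall than with cholesterol alone, at a log2 fold change of 3.75 ± 0.25 (SE) and an adjusted p of 3.82e-05 by limma. Over the alternatives this ranged from 3.30 without replicate 2 of cholesterol with oxgall to 4.56, or 23.7-fold, with 75th percentile scaling. BBIF01704 was at least 6.18-fold lower, with an adjusted p of 1.92e-05, and BBIF01961 at least 1.88-fold lower, with an adjusted p of 0.000547. Their fitted log2 fold changes of -3.53 and -1.49 ranged from -4.14 to -2.44 and from -1.82 to -0.88. BBIF01554, which rose in both comparisons against MRS, had a log2 difference of -0.18 ± 0.22 (SE), which did not pass the test, with an adjusted p of 0.717, and whose sign turned under 3 alternatives.

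Among the 140 probes that rose against MRS in the presence of oxgall and were not called with cholesterol alone, 72 were also higher than with cholesterol, and of the 191 such falls 78 were also lower. For the others no difference between the treatments was found. Of the 223 shared rises, 13 were higher and 6 lower with oxgall than without, and of the 197 shared falls 48 were lower still. Of the 72 probes that fell with cholesterol only, 20 were higher with oxgall. The comparisons set together in these counts share arrays, so part of each overlap can come from the spread of those arrays. The 100 brightest probes of the treated groups had 70 in common, while those of MRS shared 75 with cholesterol and 54 with cholesterol and oxgall.

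Under all 4 scalings 75 of the higher and 69 of the lower probes were called. With 75th percentile scaling 209 probes were higher and 104 lower, and leaving out replicate 1 or 2 of cholesterol left 70 or 87 higher and 87 or 99 lower. Without replicate 1 or 2 of cholesterol with oxgall, 74 were higher in either case and 66 or 63 lower. Neither treated group was above background for 1048 of the 1822 probes, and 28 of these were among the 270 called probes.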

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

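All tests in this part were chosen after the data had been examined, and only the limits for the features of the control probe and for the calls of cholesterol with oxgall under all 4 scalings were set before those values were computed. Probes without a *B. bifidum* identifier took no part in the comparisons of the report. Of these 80 probes, 5 were above background on both arrays of a treated group and at least 2-fold brighter there than on either MRS array.

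The brightest was the manufacturer's negative control NC-bacteria-5-4. Its scanner intensity was 398.75 and 494.5 on the MRS arrays, 2793.5 and 4235.75 with cholesterol, and 6981.5 and 15486.25 with cholesterol and oxgall. The log2 change against MRS was 2.95 with cholesterol and 4.55 with cholesterol and oxgall. A general rise of the background is argued against by the other 46 negative controls. Their median log2 change was -0.295 with cholesterol and -0.476 with cholesterol and oxgall. Their median lies near the floor, so it cannot exclude a gain in signal. The 95th percentile of the 47 negative controls was 298.9 and 310.2 in MRS. It was higher on all treated arrays, at 475.6 and 579.5 with cholesterol, and 374.7 and 345 with cholesterol and oxgall. A few defective features are argued against by the mean over its 6 features, which was at its furthest 0.948 times their median on the 4 treated arrays. Binding of a *B. bifidum* transcript to this probe stays open and was not tested, and no biological explanation was tested.

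The other 4 are given as values. A submitted probe without *B. bifidum* identifier was at 350.5 and 390 in MRS, 963 and 2584 with cholesterol, and 1740.5 and 3261.5 with cholesterol and oxgall, a log2 change of 2.69 for the last group against MRS. The manufacturer's probe QC-5prime was at 330.25 and 420.75, then 1457.75 and 2523.5, then 1115.5 and 1184, a log2 change of 1.62. QC-3prime was at 347 and 394, then 1229.25 and 1528, then 882 and 619.5, a log2 change of 0.999. The negative control Neg-lambda6 was at 302 and 317, then 693 and 707, then 472 and 353, a log2 change of 0.40, and was highest with cholesterol.

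The changes against MRS were weighed against the narrower range of signal of the MRS arrays, because quantile normalization and cyclic loess remove a range that differs by a smooth function of brightness, and no such range moves probes both ways under every scaling. For cholesterol with oxgall, 87 rises and 22 falls among the 341 probes above background on all 6 arrays were called under all 4 scalings, which argues against the range as the whole cause. For cholesterol alone 52 such rises and 0 such falls were called under all 4. All of these went up, so the test of moves both ways cannot decide for this comparison. Under both quantile normalization and cyclic loess, 52 such rises and 64 such falls were called. Changes of other probes can also make rises and falls under these scalings, so both stay open with cholesterol alone. Different incubation times of the MRS and treated cultures cannot be told apart from the treatments for the 420 probes called the same way in both comparisons against MRS, since no time is given for MRS, and a response to cholesterol itself stays open.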

How the results depend on the processing

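The calls under all 4 scalings, the mean over features and the restriction to probes above background on all 6 arrays were chosen after the data had been examined. In what follows, counts are in the order cholesterol against MRS (549 probes), cholesterol with oxgall against MRS (767) and cholesterol with oxgall against cholesterol (270). Median centring gave 317, 449 and 155 probes, of which 84.5%, 76.6% and 50.3% rose, and 75th percentile scaling gave 1021, 658 and 313, of which 16.7%, 37.5% and 66.8% rose, where quantile normalization gave 48.3%, 49.3% and 48.9%. With 75th percentile scaling limma estimated 1 variance for all probes. Calls under all 4 scalings numbered 136, 306 and 144. Only probes above background on all 6 arrays gave 151, 216 and 115, with 341 probes tested, and a limit of 2 on the fitted fold gave 164, 340 and 151. Leaving out 1 array gave 256 to 547, 481 to 769 and 137 to 328 probes. The lone array of a group was then assumed to vary like the other groups. The lowest counts came without cholesterol replicate 2 for the first comparison and without cholesterol+oxgall replicate 2 for the others. Other counts left by 1 array with a change over 1.5 times were 268 without cholesterol replicate 1 in the first comparison, and 157 and 140 without the first array of cholesterol and of cholesterol with oxgall in the third. The correlation of the responses was 0.661 with median centring and with 75th percentile scaling, 0.603 with cyclic loess and 0.68 over probes above background on all 6 arrays, and it was 0.671 to 0.74 when 1 array was left out, against 0.72. Apart from the smaller number of probes or arrays or the stricter limit, the cause was not tested. Of the called probes, 0 were called in the opposite direction under any alternative run. The processed values of the authors gave 430, 666 and 210 probes, of which 417, 655 and 202 were also called from the scanner values. With the replicate block the counts were 667, 854 and 348. The deviations of same-numbered arrays correlated across probes at 0.216, 0.063 and 0.337 in these comparisons. With only 2 pairs in each, this does not settle whether same-numbered arrays share more than a number. Over the 4 named probes, 195 of 207 values under an alternative kept their direction and their side of the threshold, and 9 kept their direction and no longer passed, all with cholesterol against MRS. The other 3 were those of BBIF01554 with oxgall against cholesterol, not called in any, where -0.18 became 0.07 with 75th percentile scaling, 0.08 with cyclic loess and 0.14 without cholesterol replicate 2. Averaging or taking the median of several probes of a gene made no difference, as each identifier has 1 probe, and the alternatives for the gene lists were not run, since the lists had 0 members. Signal over background limits the rest, with 941 probes above background on no array.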

Other observations

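The tests of list order and of the gap between identifiers were chosen after the correlation between neighbours had been seen, and the counts of runs were also added then. Probes with consecutive identifier numbers tended to change together. Among 992 pairs of neighbours, the log2 fold changes of cholesterol with oxgall against cholesterol correlated across pairs at r of 0.258. The value was 0.211 for cholesterol with oxgall against MRS and 0.085 for cholesterol against MRS. Shuffling the identifiers gave a permutation p of 1e-05 for the first and second, the smallest that 100000 shuffles can give, and 0.0072 for the third, or 1.5e-05, 1.5e-05 and 0.0072 after Benjamini-Hochberg adjustment over the 3 comparisons. Pairs of probes are not independent replicates, and the difference between the comparisons was not tested.

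Runs of at least 3 measured identifiers in order, all called the same way, numbered 15 for cholesterol with oxgall against cholesterol, with 55 probes, where shuffled identifiers gave 1.33 on average and 7 at most in 1000 shuffles. For cholesterol with oxgall against MRS there were 43 runs with 167 probes, where shuffling gave 26.6 on average and 43 at most. For cholesterol against MRS there were 11, where shuffling gave 10.5 on average and 21 at most. The one-sided permutation p-values adjusted over the 3 comparisons were 0.003, 0.0045 and 0.48 in this order. Restricted to calls made under all 4 scalings, the runs numbered 3, 10 and 0 in the same order, against 0.197, 2.61 and 0.438 on average and 2, 9 and 3 at most by shuffling. The longest run, of 17 probes, fell with cholesterol and oxgall against MRS, by log2 fold changes of -0.60 to -2.50. Of its probes 15 were above background on all 6 arrays, 4 also fell with cholesterol alone and 8 were lower with oxgall than without, but only 2 were called under all 4 scalings. A run of 8 probes fell with cholesterol alone, by -0.72 to -1.33, and 6 of these were higher with oxgall than with cholesterol. Their median log2 fold change with cholesterol and oxgall against MRS was 0.04. This fall is among those that depend on the scaling, with 0 of the 8 called under all 4. The comparisons set together for these runs share arrays, so part of such overlaps can come from the spread of those arrays.

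For cholesterol with oxgall against cholesterol, the order of the probes in the list is argued against as the source of the correlation of neighbours, since it was 0.243 among 539 pairs listed over 100 rows apart, where 95% of shuffled values lay between -0.091 and 0.08. For cholesterol against MRS it was 0.06 among such pairs, within the shuffled range of -0.084 to 0.085. Probes in neighbouring rows with identifiers over 3 apart correlated at -0.001 there, which speaks against list order, so these values together do not settle it for that comparison. In the comparison of the treatments, similar brightness of neighbours is argued against by a correlation of 0.249 after the trend on mean level was removed. Co-transcription of neighbouring genes is a hypothesis in line with a correlation of 0.258 at a gap of 1, 0.211 at 2, 0.091 at 3 to 5 and 0.05 at 6 to 10, and of 0.005 at 30 to 60, within the shuffled range of -0.012 to 0.01. That the numbers follow the order of genes in the genome is an assumption not checked here, and the place of each feature on the array surface was not known.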
